A study of Arabidopsis thaliana with 3 samples.

How the data were processed

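Total RNA from leaf, inflorescence and silique of wild-type Arabidopsis thaliana (Col-0) was extracted on silica columns and treated with DNase, per the labels' protocols, and sequenced with strand information kept, per the series title. Each organ gave 1 library, so 3 libraries were compared. The deposited values are FPKM, fragments scaled to transcript length and to the library total, per the file headers, with 1 value per identifier. TopHat and the TAIR10 build are named by the submitters' processing notes. The TopHat version, the quantification tool, the annotation, the denominator of the FPKM and any scaling between libraries are not given in the sources used here. FPKM divides by transcript length and by library total, so a few very abundant transcripts lower all other values of a library, and a very short locus takes a large value from few fragments.

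Each library lists the same 33857 identifiers, called loci here, with an interval and a value, without gene names or strand. They lie at 30747 distinct positions, since some share an interval. Identifiers run through each chromosome in 2 ascending series. Loci were named by position from a reference gene table of assembly TAIR10.1, used for names and gene types only. With 1 added to the start, between 36.6% and 43.1% of the starts of loci alone at their position on chromosomes 1 to 5 equalled an annotated start, against 0.6% or less as given. A locus was named when its position held 1 identifier, when exactly 1 reference gene had at least 50% of its length in the locus and covered at least 50% of it, and when that gene lay in no other locus by that measure. This named 26029 loci. It left 5653 identifiers at positions that several share, 1509 with several or partly overlapping genes, 514 with no reference gene, and 152 on the mitochondrial genome, where starts did not match. Positions printed are those of the files, counted from 1.

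Ratios are on the log2(FPKM + 1) scale, which understates the ratio of low loci. A locus was counted as different between organs when the ratio was at least 4 and the higher value at least 5 FPKM. An organ-enriched locus had at least 5 FPKM and at least 4 times the higher of the other organs. Detection meant at least 1 FPKM. Before the data were examined, 25 gene lists with 453 entries were fixed, along with these rules. Some genes stood in several lists, so the lists are not independent. NST1 and NST3 were in the valve margin and secondary wall lists, and CRC in the floral identity and nectary lists. A list's median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins, drawn from named nuclear loci with at least 1 FPKM in any organ. This percentile describes these libraries and is not a p-value. The median log2 ratio of a list covered only its members with at least 1 FPKM in any organ. Counts of members and median FPKM covered all named members. Lists with under 5 detected members, those for root and for small RNA precursors, were given by member values only. Of the entries, 355 were at named loci, 95 were at loci that could not be named, and 3 were left out because the reference gives another symbol to their code. Among the lists, those for reference genes, root, pollen, tapetum and stress served as markers of other tissues or of handling.

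The genes named were set by rule: for each organ the 10 organ-enriched named loci with the largest ratio among those with at least 20 FPKM, the 5 loci with the highest value and the 3 noncoding organ-enriched loci with the largest ratio, and for each list the 4 members with the largest span between organs and members at least 4-fold against the list's median. The members so picked from the stomatal and meiosis lists are printed only in part. TGG1, TGG2, PR1, HSP90.1, CLV1, LHY, TFL1, FUL, RPL, ADPG2 and CRU3 were named after their values were seen. The comparison of antisense with sense transcripts that had been planned was not made, since no strand is given with the values.

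The depth of each library is unknown, and whole fragments could not be recovered because low values show no common step. As a rough guide, the mean of FPKM times kilobases over the 100 lowest values above 0, at loci alone at their position, of 1500 to 2500 bp, was 0.0455 in leaf, 0.0316 in inflorescence and 0.0444 in silique. Alternatives changed the pseudocount, the minimum, the fold, the detection floor, the scaling between libraries, the background and the centre of the lists. The counting and list steps were tested on simulated data for leaf against inflorescence with 25141 genes. All 50 genes simulated at each of 6-fold, 12-fold and 24-fold were counted and none of 50 at 2-fold. None of 24941 unchanged genes was counted, and 5.58% of 197 random lists fell outside the central 95%. Unchanged genes had the same simulated level in every library, with random counting noise only, and the changed genes were taken from those of at least 20 FPKM. The simulation therefore checks the steps and gives no error rate for libraries without replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.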

Results

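Transcript levels were measured by strand-specific RNA sequencing in 3 organs of wild-type Arabidopsis thaliana of the Columbia accession (Col-0): leaf, inflorescence (the flowering shoot tip with its buds and open flowers) and silique (the fruit with its developing seeds). The design compared the organs with each other. There was 1 library per organ, so no difference given below has a replicate check, and no p-value or error was computed. Plants had been shot with bare gold particles as a mock transformation before the organs were taken, in the same way for all 3 organs. Values are in FPKM, fragments scaled to transcript length and library total, for 33857 identifiers, called loci here, the same in each library; some share 1 position. The number of fragments behind a value is unknown, and an exact 0 can be a failed estimate as well as an absent transcript, so such loci are described as listed at 0. Positions are on the TAIR10 build, as the files give them; a locus spans exons and introns together, and exon structure was not analysed here.

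Fewer loci were detected in leaf than in the reproductive organs. At a floor of 1 FPKM, 18451 loci (54.5%) were detected in leaf, 20910 (61.8%) in inflorescence and 20678 (61.1%) in silique. All 3 organs shared 17234 of these loci. Inflorescence and silique shared 1880 loci that were under the floor in leaf, and 1465 loci reached it in inflorescence alone, 1240 in silique alone and 562 in leaf alone. The leaf library drew more of its summed FPKM from a few loci: the 100 highest loci took 37.6% in leaf, 26.1% in inflorescence and 27.7% in silique. RBCS1A, a small subunit gene of the carbon-fixing enzyme Rubisco (chromosome 1, 25048158 to 25049424), was at 21488 FPKM in leaf, 7169 in inflorescence and 10868 in silique. In silique SESA3, a seed storage albumin gene (chromosome 4, 13611796 to 13612563), reached 22796 FPKM, and GILT (chromosome 4, 7583272 to 7584630) reached 14448, against 849 in inflorescence and 15.6 in leaf. Loci encoded by the chloroplast genome took 0.1003% of the summed FPKM in leaf, 0.0393% in inflorescence and 0.128% in silique, and mitochondrial loci 0.0709%, 0.0881% and 0.0926%.

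In leaf and inflorescence, the 4 highest values belonged to loci at positions that several identifiers share, which could not be given a gene name. In silique the named loci AT2G01021 and SESA3 were above them. XLOC_001474 (chromosome 1, 9481532 to 9482912) was at 100608 FPKM in leaf, 45904 in inflorescence and 17080 in silique. XLOC_012617 (chromosome 2, 10135605 to 10137561) was at 45430, 44782 and 19846. XLOC_011558 (chromosome 2, 1933177 to 1934212) was at 27503, 8535 and 5892, and XLOC_018272 (chromosome 3, 5179413 to 5181586) at 21690, 2454 and 1310. XLOC_022342 (chromosome 4, 11480344 to 11482760) was listed at 0 in leaf and at 10890 in inflorescence and 2961 in silique. The named locus AT2G01021 (chromosome 2, 6571 to 6672) was at 1595 FPKM in leaf, 7920 in inflorescence and 25172 in silique. It is narrower than 200 bp, a width at which few fragments can give a large FPKM. Loci of that width above 0 had a median of 31.9 FPKM in silique, far under this value. The number of fragments and the RNA behind it were not determined, so its order of organs is not interpreted.

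Across 23036 loci with at least 1 FPKM in any organ, silique and inflorescence were the closest pair, with a Pearson r of 0.764 and a Spearman rho of 0.778 on log2(FPKM + 1). Leaf and inflorescence had an r of 0.729 and a rho of 0.736, and leaf and silique an r of 0.728 and a rho of 0.731. The ranking by r was nearly lost at a pseudocount of 0.1, where the r was 0.691 for silique and inflorescence, 0.690 for leaf and inflorescence and 0.686 for leaf and silique. These coefficients run across genes, which are not independent replicates. Among 12941 loci with at least 5 FPKM in every organ, the median log2 ratio was 0.16 for leaf over inflorescence, 0.08 for silique over inflorescence and 0.09 for leaf over silique, so list medians below are read beside random lists from the same libraries. Median log2 ratios of lists cover the members detected in any organ, so they can rest on fewer genes than the member counts beside them. A housekeeping set of 10 reference genes had no member that differed 4-fold in any pair. In that set UBQ10, a polyubiquitin gene, was at 1760 FPKM in leaf, 745 in inflorescence and 664 in silique, and ACT2, an actin gene, at 498, 238 and 303. ACT8 went the other way, at 115, 238 and 186, as did UBQ5, at 374, 747 and 608.

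**Figure D1:**
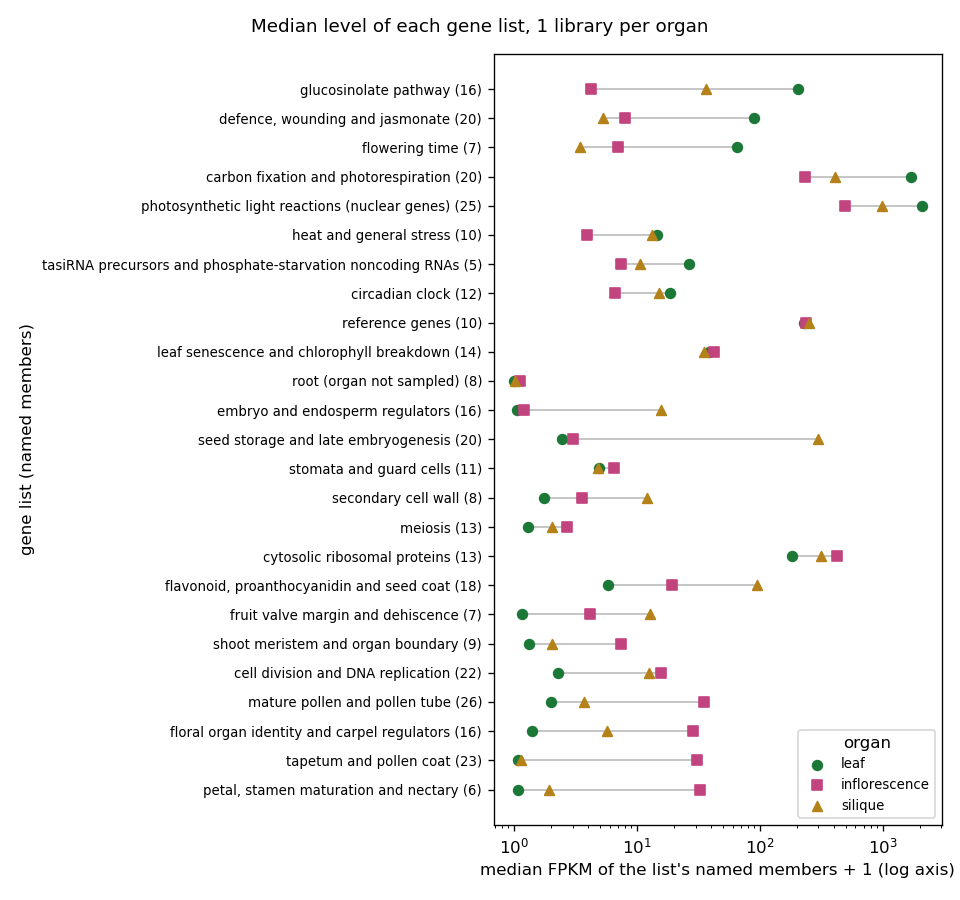
Median FPKM plus 1 (log axis) of each gene list with at least 5 named members, for leaf (circles), inflorescence (squares) and silique (triangles), with 1 library per organ and the number of named members after each list. Seed storage members had a median of 298 FPKM in silique against 1.47 in leaf and 2.04 in inflorescence, and light reaction members 2075 in leaf against 490 and 984.

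Leaf against inflorescence set a photosynthetic organ beside a shoot tip with dividing tissue, flowers and pollen. Photosynthesis, glucosinolate and defence genes were higher in leaf, and pollen, tapetum, floral identity and cell division genes were higher in inflorescence. Of 20 named genes of carbon fixation and photorespiration, 16 were at least 4-fold higher in leaf, and the median was 1707 FPKM in leaf against 234 in inflorescence. Of 26 mature pollen genes, 22 were at least 4-fold higher in inflorescence, with a median of 34.2 FPKM against 0.985 in leaf. By the fixed rule of a 4-fold difference with at least 5 FPKM in the higher organ, 1414 loci were higher in leaf and 2105 in inflorescence, out of 17444 loci that reached the minimum in either.

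Among the photosynthesis genes, CP12-2, a regulator of the Calvin cycle (chromosome 3, 23090944 to 23091566), was at 2338 FPKM in leaf and 128 in inflorescence. The photorespiratory genes GLDP1, for a subunit of glycine decarboxylase (chromosome 4, 15926670 to 15931332), and GLO1, for a glycolate oxidase (chromosome 3, 4821523 to 4824178), were at 1872 and 2489 FPKM in leaf, against 114 and 234. FBA1, a plastid aldolase gene (chromosome 2, 9128147 to 9130240), was at 1020 against 105. Of 25 nuclear genes of the light reactions, 19 were at least 4-fold higher in leaf. Among them PSBO2, of the oxygen-evolving complex (chromosome 3, 18890876 to 18892426), was at 1197 FPKM against 167, and LHCA3, an antenna protein gene (chromosome 1, 22699715 to 22701383), at 2049 against 310. The median log2 ratio was 2.81 for carbon fixation, at the 100th percentile of 10000 random lists, and 2.13 for the light reactions, also at the 100th percentile.

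The glucosinolate list, whose genes make sulphur-rich defence compounds of the cabbage family, had the widest leaf excess of the fixed lists, with a median log2 ratio of 4.19. Of its 16 members, 13 were at least 4-fold higher in leaf. CYP79F1, which starts the core of aliphatic glucosinolates (chromosome 1, 5608807 to 5611426), was at 607 FPKM in leaf and 0.692 in inflorescence. MAM1, of side-chain elongation (chromosome 5, 7703092 to 7706896), was at 721 against 1.81, CYP83A1 (chromosome 4, 7990485 to 7992311) at 662 against 3.63, and IPMI2 (chromosome 2, 17920660 to 17921689) at 460 against 2.78. The myrosinase genes TGG1 and TGG2, whose products break glucosinolates down, did not follow: they were at 640 and 720 FPKM in leaf and 1205 and 1604 in inflorescence.

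Of 20 genes of defence, wounding and jasmonate, 11 were at least 4-fold higher in leaf and 2 in inflorescence, with a median log2 ratio of 3.05. AOC2, an allene oxide cyclase gene of jasmonate synthesis (chromosome 3, 9406873 to 9407955), was at 800 FPKM in leaf and 3.50 in inflorescence. The defensin gene PDF1.2a (chromosome 5, 17907069 to 17907598) was at 280 against 0.138, and CORI3 (chromosome 4, 12310619 to 12313212) at 1029 against 47.7. The members against the list were the thionin gene THI2.1 (chromosome 1, 27198433 to 27199444), at 2.15 FPKM in leaf and 1214 in inflorescence, and the jasmonate repressor gene JAZ10 (chromosome 5, 4218888 to 4220883), at 9.16 against 66.4. The salicylate marker PR1 was at 29.8 FPKM in leaf and 0.282 in inflorescence. The stress list, a marker of handling, was also higher in leaf, with a median log2 ratio of 0.98, at the 99.6 percentile, and 3 of 10 members at least 4-fold higher. These were RAB18 at 44.8 FPKM against 3.20, RD29A at 17.5 against 1.31 and HSP90.1 at 15.8 against 1.98. Handling was not separated from the organ for either list.

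The medians of the flowering time and clock lists were also higher in leaf, with 3 of 7 flowering time genes and 3 of 12 clock genes at least 4-fold higher. SVP, a floral repressor (chromosome 2, 9579874 to 9583893), was at 130 FPKM in leaf and 6.07 in inflorescence, SOC1, a floral integrator (chromosome 2, 18807538 to 18811047), at 191 against 30.9, and FT, which encodes the mobile flowering signal (chromosome 1, 24331428 to 24333934), at 123 against 16.3. FD (chromosome 4, 17004595 to 17006287) was at 9.40 against 4.12. Over 7 flowering time genes the median log2 ratio was 2.14, and over 11 detected clock genes it was 1.41. Among clock genes, ELF4 (chromosome 2, 16734294 to 16734912) was at 123 FPKM against 21.9, GI (chromosome 1, 8061844 to 8067716) at 17.9 against 2.74, and PRR7 (chromosome 5, 637897 to 641977) at 16.98 against 2.46. TFL1, at 0.556 FPKM in leaf and 2.30 in inflorescence, and the clock gene LHY, at 1.73 against 4.46, went the other way. The time of day of collection was not given in the sources used here.

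On the inflorescence side, the tapetum list, for the anther layer that feeds pollen and makes its coat, had a median log2 ratio of -4.95, and 18 of its 23 members were at least 4-fold higher in inflorescence. GRP19, a pollen coat protein gene (chromosome 5, 2388310 to 2389249), was at 715 FPKM in inflorescence and 0.856 in leaf. GRP17 (chromosome 5, 2382468 to 2384521) was at 203 against 0.248, the lipid transfer protein gene LTP12 (chromosome 3, 19135665 to 19136675) at 241 against 0.280, and the lipase gene EXL4 (chromosome 1, 28501434 to 28503283) at 157 against 0.140. In the pollen list, the pectin methylesterase genes VGD1 (chromosome 2, 19327896 to 19330197) and PPME1 (chromosome 1, 26343369 to 26345058) were at 600 and 250 FPKM, against 14.4 and 1.01 in leaf. AGP6 (chromosome 5, 4635797 to 4636676) was at 492 against 11.998, and BCP1 (chromosome 1, 8688629 to 8689268) at 355 against 7.90.

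Of 16 genes of floral organ identity and carpel regulation, 10 were at least 4-fold higher in inflorescence, with a median log2 ratio of -4.34. PI, which with AP3 specifies petals and stamens (chromosome 5, 6829042 to 6831515), was at 141 FPKM in inflorescence and 0.310 in leaf, and AP3 (chromosome 3, 20119173 to 20121170) at 91.9 against 0.482. SEP2 (chromosome 3, 464279 to 467074) was at 141 against 0.974, and STK, of ovule identity (chromosome 4, 6236375 to 6240932), at 70.5 against 0.214. SEP4 (chromosome 2, 1129268 to 1131838) went against the list, at 65.4 FPKM in leaf and 15.2 in inflorescence. All 6 genes of the petal, stamen and nectary list were at least 4-fold higher in inflorescence. Among them were the terpene synthase gene AT5G44630 (chromosome 5, 18003255 to 18005616), at 70.3 FPKM against 0.0808, the nectary sugar transporter gene SWEET9 (chromosome 2, 16306688 to 16308252), at 46.1 and listed at 0 in leaf, and CRC, of carpel and nectary development (chromosome 1, 26007465 to 26009059), at 39.5 against 0.126. CWINV4, a cell wall invertase gene needed for nectar (chromosome 2, 15174730 to 15177870), was at 23.6 against 0.0643.

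Cell division genes had the same direction. Of 22 genes of cell division and DNA replication, 18 were at least 4-fold higher in inflorescence, with a median of 14.8 FPKM against 1.27 in leaf. KNOLLE, of the cell plate (chromosome 1, 2709632 to 2710912), was at 48.7 FPKM against 2.67, CDC20.1 (chromosome 4, 16044352 to 16046792) at 32.3 against 1.44, the mitotic cyclin gene CYCB1;2 (chromosome 5, 1859279 to 1861649) at 26.9 against 1.48, and AUR1 (chromosome 4, 15842453 to 15844536) at 34.7 against 2.18. Of 9 genes of the shoot meristem and organ boundaries, 4 were at least 4-fold higher in inflorescence, with a median log2 ratio of -2.22. The meristem gene STM (chromosome 1, 23058582 to 23061722) was at 58.3 FPKM against 2.15, KNAT1 (chromosome 4, 5147700 to 5150966) at 33.3 against 1.197, the stem cell regulator WUS (chromosome 2, 7808871 to 7810795) at 10.96 against 0.0481, and KNAT2 (chromosome 1, 26576486 to 26582431) at 6.39 against 0.490. CLV1, a meristem receptor kinase gene, went the other way, at 40.2 FPKM in leaf and 11.8 in inflorescence. None of 13 ribosomal protein genes differed 4-fold, and their median was 183 FPKM in leaf and 422 in inflorescence. The largest span among them was that of RPS18A (chromosome 1, 8067864 to 8069342), at 84.1 against 281, ahead of RPS6A at 110 against 330, RPL16A at 14.8 against 43.6 and RPS5A at 252 against 703.

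In all, 16 of 23 lists lay outside the central 95% of random lists for this pair, 8 on the leaf side and 8 on the inflorescence side. Stomatal genes were not among them, with a median log2 ratio of -0.52. The flavonoid list, at -0.77, and the seed storage list, at 0.56, lay outside, but fell inside at a pseudocount of 5 and when the mean replaced the median. The balance of the counts depended on the rule. At a minimum of 20 FPKM, 1109 loci were higher in leaf and 997 in inflorescence, at 2-fold 3355 and 3455, at 8-fold 523 and 1207, and at a pseudocount of 5 they were 870 and 969.

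**Figure D2:**
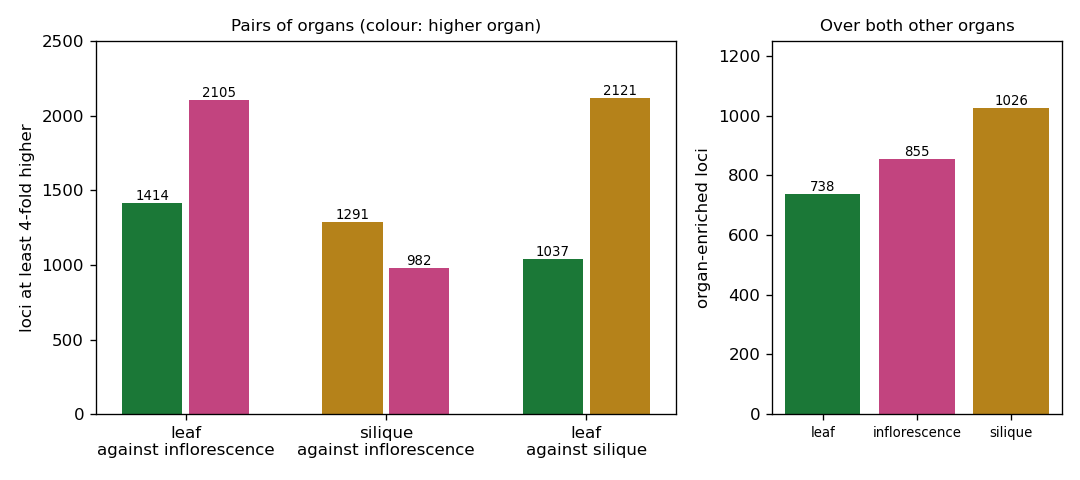
Number of loci at least 4-fold higher in each organ of a pair (left, bars coloured by the higher organ) and of organ-enriched loci, at least 4-fold over both other organs (right), from 1 library per organ. Leaf against inflorescence had 1414 and 2105 loci, silique against inflorescence 1291 and 982, and leaf against silique 1037 and 2121.

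Silique against inflorescence set the fruit with its seeds beside the flowers it develops from. Seed storage, embryo, seed coat and secondary wall genes were higher in silique, and tapetum, pollen and nectary genes were higher in inflorescence. Of 20 seed storage and late embryogenesis genes, 17 were at least 4-fold higher in silique, and the median was 298 FPKM against 2.04, a median log2 ratio of 7.08. Of 23 tapetum genes, 16 were at least 4-fold higher in inflorescence, with a median of 29.6 FPKM against 0.145. In total 1291 loci were at least 4-fold higher in silique and 982 in inflorescence, out of 17793 that reached the minimum in either.

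The storage albumin gene SESA3 was at 22796 FPKM in silique and 26.7 in inflorescence, and SESA1 (chromosome 4, 13607329 to 13608031) at 3516 against 8.85. CRA1, a 12S globulin gene (chromosome 5, 17756264 to 17758288), was at 6563 against 8.88, and OLEO2, an oil body protein gene (chromosome 5, 16173393 to 16174783), at 855 against 0.712. Of 16 embryo and endosperm genes, 10 were at least 4-fold higher in silique and none in inflorescence. EPR1, an extensin-like gene of the endosperm (chromosome 2, 11713411 to 11715696), was at 1199 FPKM against 0.715. FAE1, of seed fatty acid elongation (chromosome 4, 16494205 to 16495842), was at 58.3 against 0.0539, the embryo regulator LEC1 (chromosome 1, 7727577 to 7729617) at 42.1 against 0.193, and MYB118 (chromosome 3, 10288603 to 10290934) at 18.4 against 0.0711.

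Of 18 flavonoid, proanthocyanidin and seed coat genes, 9 were at least 4-fold higher in silique and the median log2 ratio was 2.13. BAN, which makes the tannin precursors of the seed coat (chromosome 1, 22791168 to 22792800), was at 438 FPKM against 36.1. TT10, a laccase gene that browns the seed coat (chromosome 5, 19489327 to 19492744), was at 206 against 0.915, TT7 (chromosome 5, 2560394 to 2563109) at 236 against 23.5, and MYB61 (chromosome 1, 3086159 to 3087912) at 39.6 against 2.12. Secondary wall genes had a median of 10.997 FPKM in silique and 2.57 in inflorescence, and 4 of 8 were at least 4-fold higher in silique. IRX9, of xylan synthesis (chromosome 2, 15587394 to 15589257), was at 33.6 against 3.81, COBL4 (chromosome 5, 5084704 to 5086792) at 67.0 against 7.84, and the laccase gene LAC4 (chromosome 2, 15934460 to 15937616) at 135 against 31.7. Of the 7 genes of the valve margin, where the fruit opens, 1 was at least 4-fold higher in silique: the wall regulator NST3 (chromosome 1, 11865343 to 11866950), at 11.8 FPKM and listed at 0 in inflorescence. NST3 was also among the secondary wall genes counted above. NST1 (chromosome 2, 19220727 to 19222916) was at 10.2 against 2.13, IND (chromosome 4, 41665 to 43197) at 10.1 against 3.15, and the polygalacturonase gene ADPG1 (chromosome 3, 21283338 to 21285941) at 16.1 against 7.25. Lower in silique were FUL, at 44.2 FPKM against 61.0, RPL, at 16.5 against 25.4, and ADPG2, at 0.119 against 1.79.

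Glucosinolate genes were also higher in silique than in inflorescence, with 9 of 16 at least 4-fold higher and a median log2 ratio of 2.27; CYP79F1 was at 40.1 FPKM against 0.692. Of 10 stress genes, 6 were at least 4-fold higher in silique. The medians were 2.95 FPKM in inflorescence, 12.3 in silique and 13.4 in leaf, so inflorescence was the low organ for this list. Handling was not separated from the organ in this pair either. RAB18, a dehydrin gene (chromosome 5, 26518277 to 26519242), was at 72.9 FPKM against 3.20, HSP70-4 (chromosome 3, 3991261 to 3993792) at 27.8 against 2.70, RD29A (chromosome 5, 21240849 to 21243613) at 10.5 against 1.31, and RD29B (chromosome 5, 21237056 to 21239529) at 5.03 against 0.0511. FT was at 206 FPKM in silique and 16.3 in inflorescence, against the median of the flowering time list. Both photosynthesis lists lay above random lists in silique. The median log2 ratio was 0.87 for carbon fixation, at 405 FPKM against 234, and 0.96 for the light reactions, at 984 against 490. No carbon fixation gene differed 4-fold, and 3 of 25 light reaction genes were at least 4-fold higher in silique, among them LHCB2.1 (chromosome 2, 1823240 to 1824425), at 264 FPKM against 26.5, and LHCB2.2 (chromosome 2, 1799234 to 1800392), at 194 against 21.3. These are near-identical copies that can share fragments.

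Of 26 pollen genes, 21 were at least 4-fold higher in inflorescence than in silique; VGD1 was at 600 FPKM against 39.7, PPME1 at 250 against 3.09. GRP19 was at 715 against 2.37. Of 16 floral identity genes, 4 were at least 4-fold higher in inflorescence. PI was at 141 FPKM against 3.94 in silique, while AP3 was at 91.9 against 63.3 and SEP2 at 141 against 142, and STK was higher in silique at 144 against 70.5. WUS was at 10.96 against 0.0751. SAG12, a cysteine protease gene of senescence (chromosome 5, 18613259 to 18614930), was at 345 FPKM in inflorescence and 21.4 in silique. The sugar transporter gene SWEET15 of the same list (chromosome 5, 4181042 to 4183306) was at 12.1 against 157. Cell division genes kept closer levels, with a median of 14.8 FPKM in inflorescence and 11.5 in silique and none 4-fold apart. Among 8 detected genes of meiosis none differed 4-fold; DMC1 (chromosome 3, 8097687 to 8100820) was at 9.44 FPKM in inflorescence and 13.2 in silique. Outside the central 95% of random lists lay 17 of 23 lists, 9 on the silique side and 8 on the inflorescence side. The cell division list, at a median log2 ratio of -0.56, and the stomatal list, at -0.78, fell inside when the mean replaced the median, as did the valve margin list, at 1.05.

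**Figure D3:**
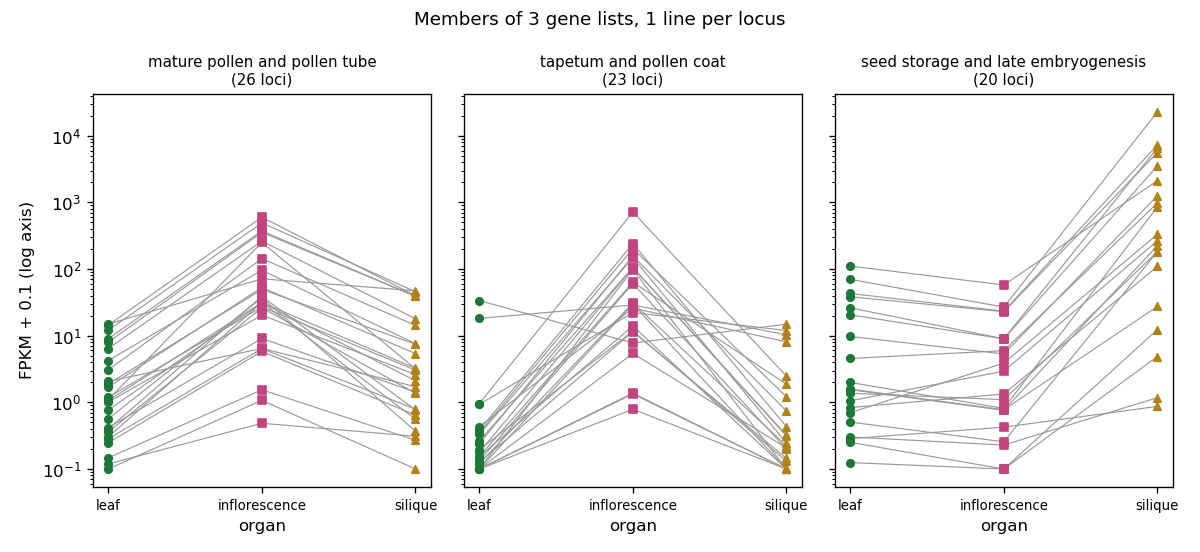
FPKM plus 0.1 (log axis) of each named member of the pollen, tapetum and seed storage lists in leaf, inflorescence and silique, with 1 line per locus and 1 library per organ. The seed storage lines rise to silique, as for SESA3 at 22796 FPKM against 70.0 in leaf and 26.7 in inflorescence, and the pollen and tapetum lines peak in inflorescence, as for VGD1 at 600 and GRP19 at 715.

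Leaf against silique compared a vegetative with a fruiting organ. Defence, glucosinolate and carbon fixation genes were higher in leaf, and seed, seed coat, secondary wall and cell division genes were higher in silique. Of 20 defence genes, 11 were at least 4-fold higher in leaf and 2, THI2.1 and JAZ10, in silique, with a median of 89.5 FPKM in leaf and 4.28 in silique. Of 18 flavonoid and seed coat genes, 14 were at least 4-fold higher in silique and none in leaf. In total 1037 loci were at least 4-fold higher in leaf and 2121 in silique, out of 17451 that reached the minimum in either. At 2-fold these counts were 3151 and 3682, and at 8-fold 375 and 1278.

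AOC2 was at 800 FPKM in leaf and 0.995 in silique, PDF1.2a at 280 against 0.345, and CORI3 at 1029 against 9.48. THI2.1 was at 544 FPKM in silique and 2.15 in leaf, and JAZ10 at 51.9 against 9.16. For glucosinolates 11 of 16 genes were at least 4-fold higher in leaf, with a median log2 ratio of 2.94; MAM1 was at 721 against 45.6. Of 20 carbon fixation genes, 8 were at least 4-fold higher in leaf, among them CP12-2 at 2338 against 309, whereas none of the 25 light reaction genes differed 4-fold, with medians of 2075 and 984 FPKM. Of 7 flowering time genes, 3 were at least 4-fold higher in leaf. SVP was at 130 FPKM against 2.43 in silique, SOC1 at 191 against 6.19 and FD at 9.40 against 0.426, while FT was at 123 against 206. Of 11 stomatal genes, 1 was at least 4-fold higher in leaf and 1 in silique. FAMA, a regulator of guard cell fate (chromosome 3, 8715236 to 8718211), was at 27.0 FPKM against 3.84, against the median of the stomatal list. MYB60, of guard cells (chromosome 1, 2819065 to 2820395), was at 9.04 against 30.0, under 4-fold. In the senescence list 2 of 14 genes were at least 4-fold higher in leaf and 3 in silique. NAP (chromosome 1, 26122139 to 26123421) was at 63.5 FPKM in leaf and 8.26 in silique, and NAC092 (chromosome 5, 15858400 to 15859788) at 44.8 against 5.94, against the list's median log2 ratio of -0.76, which SWEET15 followed at 0.384 against 157.

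On the silique side, 17 of 20 seed storage genes were at least 4-fold higher and the median log2 ratio was -7.03. Storage transcripts were also listed in leaf, with CRU3 the highest at 111 FPKM against 2111 in silique, SESA3 at 70.0, CRA1 at 26.1 and SESA1 at 20.5. Of 16 embryo and endosperm genes, 11 were at least 4-fold higher in silique, EPR1 at 1199 FPKM against 2.22 in leaf, with LEC1 and MYB118 listed at 0 in leaf. BAN was at 438 FPKM against 0.852 and TT10 at 206 against 0.0999. Of 8 secondary wall genes, 6 were at least 4-fold higher in silique, with IRX9 at 33.6 against 1.06. Of 22 cell division genes, 14 were at least 4-fold higher in silique, KNOLLE at 71.7 FPKM against 2.67. Of 16 floral identity genes, 5 were at least 4-fold higher in silique and 1 in leaf. STK was at 144 FPKM in silique against 0.214 and SEP2 at 142 against 0.974, while SEP4 was at 5.16 against 65.4 in leaf. The median of the pollen genes was low in both organs, at 0.985 FPKM in leaf and 2.73 in silique, and 2 of 26 were at least 4-fold higher in silique. Over 10 pollen genes of at least 50 FPKM in inflorescence, the median was 2.40% of the inflorescence value in leaf and 9.58% in silique. For this pair 15 of 23 lists lay outside the central 95% of random lists, 5 on the leaf side and 10 on the silique side. The senescence, pollen and ribosomal protein lists, at median log2 ratios of -0.76, -0.90 and -0.83, fell inside when the mean replaced the median.

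Organ-enriched loci, at least 4-fold above both other organs with at least 5 FPKM, numbered 738 in leaf, 855 in inflorescence and 1026 in silique, of which 504, 680 and 820 could be named. They held 14.2% of the summed FPKM in leaf, 8.01% in inflorescence and 16.6% in silique. In leaf, the ankyrin-repeat immunity gene ACD6 (chromosome 4, 8294446 to 8298602) was at 391 FPKM against 0.667 in inflorescence and 0.724 in silique. The receptor kinase gene CRK4 (chromosome 3, 16863149 to 16866145) was at 167 against 0.247 and 0.142, and AT1G66100 (chromosome 1, 24605671 to 24606537) at 220 against 0.268 and 0.209. The defensin gene PDF1.2c (chromosome 5, 17908945 to 17909507), at 112, and the pseudogene AT3G42090 (chromosome 3, 14274222 to 14274699), at 122, were listed at 0 in both other organs. AT1G74929 at 1595 FPKM, SNOR105 at 341 and the chloroplast gene psbI at 164 were also listed at 0 elsewhere, but are narrower than 200 bp.

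In inflorescence AT1G66850 (chromosome 1, 24936958 to 24937434) was at 556 FPKM against 0.763 in leaf and 1.03 in silique, AT5G22430 (chromosome 5, 7433790 to 7434935) at 612 against 0.393 and 3.44, and AT5G53820 (chromosome 5, 21853397 to 21854117) at 333 against 1.07 and 0.820. ATA27, a tapetum gene (chromosome 1, 28511168 to 28514284), was at 183 against 0.141 and 0.269, and AT1G20130 (chromosome 1, 6977753 to 6980279) at 163 against 0.120 and 0.110. GRP19 and LTP12 belonged to the same 10 loci. In silique the neighbours AT5G38160 (chromosome 5, 15225767 to 15226208) and AT5G38170 (chromosome 5, 15227638 to 15228081) were at 4782 and 2892 FPKM, against 4.64 and 3.85 in leaf and 2.74 and 1.45 in inflorescence. On chromosome 1, AT1G62000 (22913441 to 22914146), AT1G62060 (22941569 to 22942300), AT1G62070 (22943594 to 22944289) and AT1G62080 (22946242 to 22946949) were at 2393, 2326, 610 and 2694 FPKM in silique and at 7.18 or less in both other organs. ENODL3 (chromosome 4, 14032845 to 14033840) was at 487 FPKM against 0.526 in leaf and 0.251 in inflorescence. The order of the organs depended on the rule. At 2-fold the counts in leaf, inflorescence and silique were 2385, 1458 and 1719, with leaf the most, and at a minimum of 20 FPKM they were 564, 473 and 643. At 8-fold they were 268, 457 and 598, and at a pseudocount of 5 in place of 1 they were 432, 440 and 579.

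Detection of noncoding loci differed by class. Of 59 named long noncoding RNA loci, 20 were detected in leaf, 41 (69.5%) in inflorescence and 30 in silique, and of 79 miscellaneous RNA loci 35, 63 (79.7%) and 40. Of 111 loci of the class named noncoding RNA, 59, 63 and 63 were detected. Protein-coding loci were detected at 62.9% in leaf, 72.5% in inflorescence and 72.1% in silique. Of 3716 pseudogene loci, 70 were detected in leaf, 76 in inflorescence and 65 in silique, and of 445 transfer RNA loci none in any organ. The narrowest locus with a value above 0 was 102 bp in leaf, 101 bp in inflorescence and 102 bp in silique. A missing value at a shorter locus, such as a transfer RNA, can therefore not be read as absence. Of 514 loci without a reference gene, 33, 84 and 85 were detected. The noncoding RNA AT3G15536 (chromosome 3, 5260723 to 5261322) was at 12.2 FPKM in leaf against 0.259 in inflorescence and 0.318 in silique, and AT5G07322 (chromosome 5, 2313119 to 2313563) at 6.61 against 0.785 and 0.303. In silique the long noncoding RNA AT3G02345 (chromosome 3, 3253420 to 3254043) was at 24.7 FPKM against 0.271 in inflorescence and was listed at 0 in leaf. MIR858a at 17.63 FPKM, which is narrower than 200 bp, and AT1G09885 at 14.5 in silique were listed at 0 in both other organs. In inflorescence the 3 leading noncoding loci, MIR166d at 1659, SNOR108 at 416 and MIR775 at 137 FPKM, were all narrower than 200 bp and listed at 0 elsewhere. Among precursors of trans-acting small RNAs, TAS1A (chromosome 2, 11721489 to 11722468) was at 34.8 FPKM in leaf against 6.45 in inflorescence and 9.57 in silique, at least 4-fold apart only from inflorescence. TAS3 (chromosome 3, 5861491 to 5862437) was at 93.8 against 29.5 and 42.3, and TAS2 (chromosome 2, 16539384 to 16540426) at 25.3 against 19.0 and 15.4, both under 4-fold. AT4, a phosphate starvation gene of the same list (chromosome 5, 894706 to 895400), was at 6.46 FPKM in leaf, 1.52 in inflorescence and 0.828 in silique. It was at least 4-fold apart only between leaf and silique, a difference that fell under 4-fold with median-of-ratios scaling. Of 8 root marker genes, 2 were detected in any organ: the iron transporter gene IRT1 (chromosome 4, 10707426 to 10709015) was at 14.998 FPKM in inflorescence and COBL9 at 1.45.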

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

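The alternatives restricted to named loci and to loci of at least 200 bp were chosen after seeing the data. With 1 library per organ no replicate could be left out. No paired analysis was possible because each organ has 1 library and the results come from no test. For the pairs leaf against inflorescence, silique against inflorescence and leaf against silique, in that order, the counts of loci past the fold rule were 1839, 1184 and 1688 at a pseudocount of 5, 2106, 1352 and 1904 at a minimum of 20 FPKM, 6810, 4497 and 6833 at 2-fold, and 1730, 1190 and 1653 at 8-fold. Organ-enriched loci in leaf, inflorescence and silique numbered 432, 440 and 579 at a pseudocount of 5, 2385, 1458 and 1719 at 2-fold, and 268, 457 and 598 at 8-fold; at a minimum of 20 FPKM inflorescence had 473 and silique 643. Stricter rules lower and looser rules raise such totals by construction. Why leaf passed inflorescence in organ-enriched loci at 2-fold and at 20 FPKM, and in loci past the fold rule at 20 FPKM, was not tested. At a minimum of 5 FPKM the Pearson r was 0.629, 0.668 and 0.620 for the same pairs, and at a pseudocount of 0.1 it was 0.690, 0.691 and 0.686, so the pairs were nearly tied; the cause was not tested. Under the 3 scalings every count stayed within 1.5 times its value. The scaling without the 100 highest and the organelle loci moved all log2 ratios of leaf over inflorescence by -0.26. Among list medians under the alternatives, 602 kept their side of the central 95%, 16 fell inside it, 3 left it and none changed sign while called. The list of valve margin genes in silique against inflorescence fell inside under 3 alternatives. Of the ratios of named loci, 25 fell under 4-fold, mostly at a pseudocount of 5. The planned antisense alternatives were not run. Without counts, precision at low values is unknown.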

Other observations

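All tests in this part were chosen after the result was seen, except that on identifiers that share a position. Gene families were also grouped by symbol, after the data were examined, and those printed here were picked from 94 families for their counts. Of 16782 detected named nuclear loci, 2.997% were leaf-enriched, 4.05% inflorescence-enriched and 4.86% silique-enriched, and 29 of the families had no enriched member. The counts per family were not tested against this background. Of 73 detected LCR genes, which encode small cysteine-rich proteins, 27 were silique-enriched, 18 inflorescence-enriched and 0 leaf-enriched, and of 25 detected SCRL genes, of the same kind, 8, 12 and 0. Of 17 detected CRK receptor kinase genes, 6 were leaf-enriched and none was enriched elsewhere; their median log2 ratio for leaf against inflorescence was 1.91. Of 45 detected WRKY transcription factor genes, 5 were leaf-enriched and none elsewhere, and of 23 RLP receptor-like protein genes 5 were leaf-enriched and 1 in each other organ. In inflorescence, 5 of 14 SKS genes, 4 of 11 PERK genes and 5 of 17 RALFL peptide genes were enriched. In silique, 4 of 10 laccase genes (LAC) and 4 of 14 fasciclin-like arabinogalactan genes (FLA) were enriched. Of 112 detected EMB genes, named for embryo-defective mutants, none was enriched in any organ.

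Pollen transcripts were listed in the leaf library at a low level. Over 10 pollen genes of at least 50 FPKM in inflorescence, the median leaf value was 2.40% of the inflorescence value, with a range from 0.401% to 20.8%, against 0.103% over 10 tapetum genes. Carry-over from the inflorescence library would bring both sets alike, but the tapetum median was 0.0428 of the pollen median, which argues against it, and carry-over from the silique library is argued against by 7 seed storage genes of at least 1000 FPKM in silique, whose median leaf to silique ratio was 0.0182 of that of the pollen genes. A candidate source is pollen shed onto leaves: 19 pollen genes kept a leaf to silique ratio near 0.325, 18 of them within 2-fold, with an SD of 0.695 on the log2 scale. Most of the 23036 loci with at least 1 FPKM in any organ lay within 2-fold of equal values in leaf and silique. Their median absolute difference was 0.709 on log2(FPKM + 1). The pollen spread was taken without the added 1 and around its own median, so the 2 measures are unlike. How unusual the steady pollen ratio is was therefore not measured, and it does not tell shed pollen from expression in leaf. Low expression in leaf itself was not tested and stays open.

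Seed storage transcripts were listed in leaf as well, at a median of 0.591% of the silique value over 7 genes of at least 1000 FPKM in silique, with a range from 0.307% to 5.25%, the latter CRU3. Carry-over from the silique library would give every silique locus at least its own share, yet the third lowest share among 16 loci at least 20-fold higher in silique, which leave out CRU3, was 0.133%, 0.225 of the storage median, which argues against it as the whole cause. At those 16 loci the leaf to inflorescence ratio had a median of 2.23 and an interquartile range of 0.676 on the log2 scale, with 14 loci within 2-fold. Outside lay AT1G56100, at 2.04 FPKM in leaf and 109 in inflorescence, and LCR73, at 3.19 and 54.5. Either 1 source of seed RNA in both libraries or carry-over from silique into both may give a steady ratio, so it does not tell them apart. Expression of storage genes in leaf and inflorescence was not tested.

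The lower number of loci detected in leaf could have technical causes. At a floor of 5 FPKM, 57.6% of the gap to inflorescence and 62.7% of that to silique were left. At 10 FPKM the organs were closer, with 12073 loci in leaf, 12516 in inflorescence and 12656 in silique. At 100 FPKM leaf had the most, at 1839 against 1428 and 1809. The part left thus depended on the floor, which was chosen after the values were seen, and depth stays open. Rescaling without the 100 highest and the organelle loci left 105% of the gap to silique. The sum of the remaining loci was not lower in leaf, with a factor of 1.08 against 1.02 in silique. For this gap, that argues against the removed loci as the cause. Abundant loci below them were not tested, and the gap to inflorescence was not rescaled. Of 1880 loci under 1 FPKM in leaf alone, 76.7% had a leaf value above 0, so failed estimates listed at 0 account for at most 438 of them. Fewer active genes in leaf, a difference between organs that the design names, stays open and untested, and with 1 library per organ the organ and the library are not separable.

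Organ-enriched loci lay beside each other more often than by chance placement. Among named nuclear loci 200 adjacent pairs were enriched in the same organ, against a median of 64 and a highest of 93 in 1000 shuffles of the labels. The runs of 5 and 4 loci included GRP14 to GRP20 in inflorescence (chromosome 5, 2377710 to 2391075) and SESA1 to SESA4 in silique (chromosome 4, 13607329 to 13614283), which are tandem copies; how much of the excess tandem copies give was not tested.

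The hypothesis that identifiers that share a position, in opposite series, move together between organs was tested over 1743 pairs. The Pearson r of their log2 ratios was 0.141 for leaf against inflorescence, above the highest of 1000 shuffles, 0.0840. Adjacent named loci that do not share a position had an r of 0.120, so the relation was not particular to overlap.

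At 70 loci leaf was listed at 0 while both other organs had at least 10 FPKM, against 6 such loci for inflorescence and 8 for silique. The 70 loci are part of the 2105 and 2121 loci counted as higher in inflorescence and silique than in leaf. Failed estimates among them would raise those counts. Organ-enriched loci with both other organs listed at 0 numbered 25 in leaf, 107 in inflorescence and 84 in silique. Of 1288 loci narrower than 200 bp, 52, 78 and 59 had a value above 0 in leaf, inflorescence and silique.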
